A study of Mus musculus with 5 samples.

How the data were processed

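The data are a gene expression table of RAW264.7 cells with Renilla luciferase alone (control) or with Renilla luciferase and mouse Cd137, made from RNA selected with oligo-dT beads, per the labels. Groups and replicate numbers were taken from the sample titles. The table used here has columns for 3 libraries, control replicate 2 and CD137 replicates 2 and 3.

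The authors deposited 1 FPKM value per gene and library, rounded to 0.01, per the file headers and the values. HISAT2, Bowtie2, RSEM and the build mm10 are named in the submitters' processing notes, without roles or versions; strandedness and read length are not given in the sources used here. The deposited table lists 21990 genes by Entrez ID and symbol, of which 5987 have no value in any of the 3 libraries; 1 further line, a broken-off annotation, was left out, and 16003 genes were used. The authors' log2 ratios between pairs of libraries equal the log2 ratio of the deposited FPKM where both are above 0. The authors' p-values come from a Poisson test on 2 libraries, per the file headers, and the adjusted values beside them, which exceed 1 for some genes, were treated as a score. FPKM is relative to the library total, so a shift of very abundant genes would move all others; 7.7 to 8.0 percent of the FPKM total lay in the 10 highest genes of each library. Gene coordinates are those of the table. Of 15896 Entrez IDs found in RefSeq's annotation of GRCm38.p6, the same assembly as mm10, 99.6 percent overlapped their reference gene on the same chromosome and 10429 had the same start.

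Depth was recovered from the p-values. Each was reproduced as 2 times the smaller tail of the conditional Poisson distribution of the reads in 2 libraries, which allows whole reads (or fragments; the table does not say which) to be solved for. A unique solution was found for 14099 genes, 88.1 percent of those with an FPKM and 95.1 percent of those at 1 FPKM or more in some library. In simulated data for 600 genes, 98.7 percent were recovered and 99.8 percent of these were right. The depths estimated from 151 genes were 0.983 and 0.988 of the control in CD137 replicates 2 and 3. Intervals computed from recovered reads cover counting error only.

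The planned test for counts could not be used because the table holds FPKM, and the test planned for that case was limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, on log2(FPKM + 1), over all genes with a value, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit of 1 control against 2 CD137 libraries has 1 residual degree of freedom. A fit, also planned, that keeps only expressed genes, at 1 FPKM or more in at least 1 library, was used to say which genes rose or fell, because the fit of all genes made 0 calls; that use was chosen after seeing both fits, several further fits run to explore the data, and the simulation. Both were tested on simulated data with 200 genes changed by known folds, a spread of 2.14 percent beyond counting, and the means of the real genes. In the simulated comparison the fit of 15603 genes recovered 0 percent of the changed genes at any fold. The fit of 10632 expressed genes recovered 4, 70, 92 and 90 percent of genes changed 1.2-fold, 1.5-fold, 2-fold and 4-fold, with 0 false calls. When no gene was changed but each culture was given its own spread of 10 percent, shared by the CD137 libraries, the fit of 10641 expressed genes called 2223 genes, so the calls depend on the control culture varying no more than the CD137 libraries do.

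Gene lists, 36 in all, were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01, with a variance trend, where at least 5 members were measured, leaving out Tnfrsf9, and beside it with an estimated correlation and with fry. The version with an estimated correlation draws on the 1 residual degree of freedom and so has little power here. In simulated data camera at the preset called the 1 moved list of 36 and 0 unmoved lists. Those lists were random genes simulated independently and without culture spread. False calls for lists of genes that vary together, or from a differing control culture, were therefore not tested. Terms from the table with 10 to 300 genes were tested with camera at the preset and at an estimated correlation, not with fry; KEGG terms are reported, and of 6399 GO terms 271 were called at the preset and 0 with an estimated correlation. Members of a list are counted as past the threshold in the fit of expressed genes, and in the fit of all genes adjusted over the list alone.

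Genes were named by a rule fixed before the data were examined: Tnfrsf9; the 10 genes with the largest increase and decrease among those past the threshold with a mean of at least 50 reads (estimated here from FPKM and transcript length) in the higher group and both CD137 libraries on the same side of the control, passing over predicted genes; up to 4 members of each list with the smallest p in the fit of all genes (8 for 5 lists: osteoclast, NF-kB, TNF superfamily, chemokine and adhesion); up to 3 most highly expressed members of a list; and, where fewer than 5 genes passed in a direction, the 5 with the smallest p. The second part was applied to the fit of expressed genes, because the fit of all genes gave none. Of the 223 genes this rule allows, 111 are printed, and which ones was chosen after seeing the data; 1 gene the rule allows is withheld and not reported here. Some epithelial genes and the genes between Car6 and Tnfrsf9 are named outside the rule. Alternatives were another pseudocount (0.1), the filter, scalings, moderation settings, limma-voom on recovered reads, and leaving out each CD137 library. Those set out before the data were examined were the pseudocount, the filter, leaving out libraries, and, for lists, the estimated correlation and fry. edgeR and DESeq2 were not used, since they model counts. Python 3.11.15 with scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.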

Results

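Messenger RNA was profiled in RAW264.7 cells, a mouse monocyte/macrophage line that can be differentiated into osteoclast-like cells. The control cells expressed Renilla luciferase alone, and the CD137 cells expressed Renilla luciferase together with mouse Cd137. CD137 is a co-stimulatory receptor of the TNF receptor superfamily, encoded by Tnfrsf9. Of the 5 samples of the series, 2 are controls and 3 are CD137 samples. The values analysed here come from 3 libraries, control replicate 2 and CD137 replicates 2 and 3; control replicate 1 and CD137 replicate 1 were not analysed here. Expression was given as FPKM (fragments per kilobase of transcript, scaled to mapped fragments) for 16003 genes. Estimated depth in CD137 replicates 2 and 3 was 0.983 and 0.988 of that in the control. The comparison asks how the transcriptome of these cells differs when Cd137 is introduced, in a study concerned with the migration of monocytes and macrophages and their differentiation into osteoclasts. The control is a single library, so its values carry no replicate error, and CD137 values are means ± SD of 2 libraries.

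Tnfrsf9 (gene ID 21942) checks the labels. It lies on chromosome 4 from 150920155 to 150946104 in mm10, on the plus strand. It was at 5.06 FPKM in the control, 364 FPKM in CD137 replicate 2 and 370 FPKM in CD137 replicate 3. The CD137 mean of 367 ± 4.00 FPKM (SD, n = 2) was 72.6-fold above the control. Fragments from the introduced sequence and from the endogenous gene are not separated in these values.

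The CD137 libraries resembled each other far more than either resembled the control. Across 16003 genes the Pearson correlation of log2(FPKM + 1) was 0.999 between CD137 replicates 2 and 3, and 0.992 between each of them and the control; genes are not independent replicates. At least 2-fold differences on that scale were found for 20 genes between the CD137 libraries, against 162 and 159 genes between the control and CD137 replicates 2 and 3. Over 9350 genes with a mean of at least 100 recovered fragments, the SD of the log2 difference was 0.10 within the CD137 group and 0.33 and 0.34 against the control. The CD137 libraries still differed by more than counting noise, with a chi-square of 1.67 per gene where counting alone gives about 1, and were kept as separate samples. In the authors' deposited table, a Poisson test on the reads of these pairs gave an adjusted p under 0.05 to 223 genes between the CD137 libraries, and to 6269 and 6221 genes between the control and CD137 replicates 2 and 3. Such a test compares libraries, not conditions.

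**Figure D1:**
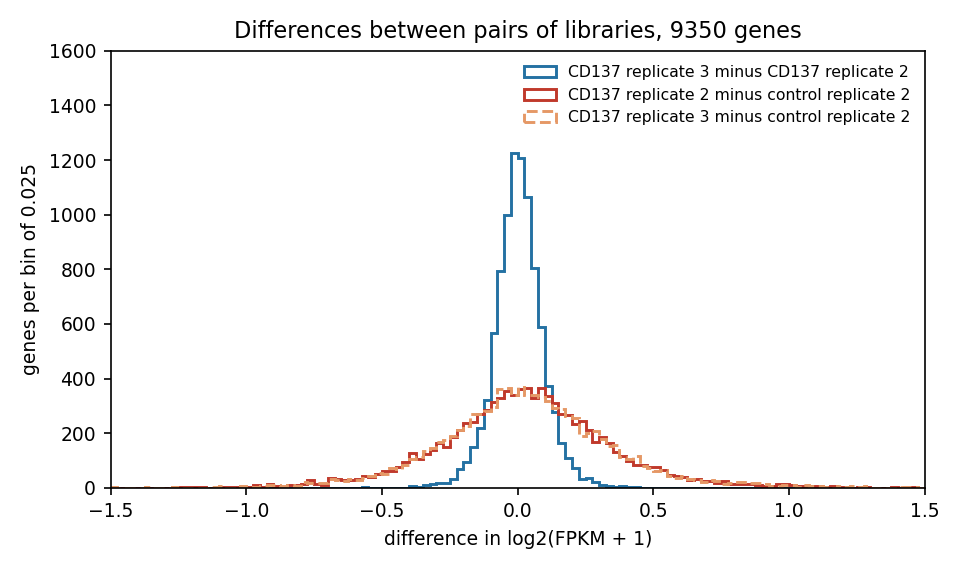
Histograms of the difference in log2(FPKM + 1) between pairs of libraries, in bins of 0.025, for 9350 genes with a mean of at least 100 recovered fragments. The SD is 0.10 between the CD137 libraries (blue) and 0.33 and 0.34 between the control and CD137 replicates 2 (red) and 3 (dashed).

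Among the genes with the largest differences, the higher ones in CD137 cells included Car6, Gstt1, Il23a, Cd40, Lcn2 and Mmp9, and the lower ones Cx3cr1, Mcm6, Lyz2 and Cxcl14. No gene passed an adjusted p of 0.05 in the limma fit of all 16003 genes, where the smallest adjusted p was 0.0802 and 5281 genes had an unadjusted p under 0.05. In the limma fit restricted to 10720 expressed genes, those with at least 1 FPKM in some library, 4563 genes passed, 2614 higher and 1949 lower in CD137 cells. Both CD137 libraries lay on the same side of the control for all 4563, which the test itself required. A gene whose CD137 libraries straddle the control has too large a spread to pass. In what follows, "rose" and "fell" are used for genes past the threshold in this fit of expressed genes, a convention chosen after seeing both fits, and none of them passed in the fit of all genes. The median absolute log2 fold change of the 4563 genes was 0.37 on the log2(FPKM + 1) scale, which understates the change of low genes. On that scale 875 changed at least 1.5-fold and 147 at least 2-fold, 114 of them higher and 33 lower; the 2-fold count was 312 with a pseudocount of 0.1 and 450 with limma-voom on recovered reads. With 1 control library the spread came from the CD137 libraries alone, and the control was assumed to vary as they do. In simulated data without any effect, the control was given a culture spread of 10 percent. The CD137 libraries were given another of 10 percent, shared between them. This gave 2223 calls among expressed genes. Nothing in the labels says that the CD137 libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

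The 5 smallest p-values among higher genes in the fit of all genes, where none passed, belonged to Tnfrsf9, Car6, Angptl6, Cp and Nfkb2. Car6, a secreted carbonic anhydrase (gene ID 12353, chromosome 4 from 150187015 to 150201135), was at 15.5 FPKM in the control and 102 ± 1.26 FPKM in CD137 cells. Its log2 fold change was 2.64 ± 0.04 (SE, adjusted p = 0.000129 among expressed genes). Gstt1, a glutathione transferase, rose from 0.60 to 14.3 ± 0.50 FPKM, and Il23a, which encodes the p19 subunit of interleukin-23, from 0.75 to 10.6 ± 2.17 FPKM. The lipocalin Lcn2 rose from 0.27 to 4.04 ± 0.11 FPKM. Avil, an actin-binding protein of the gelsolin family, rose 3.94-fold and Cdsn, known as a corneodesmosome protein, 6.06-fold. Angptl6 rose 2.93-fold and Cp, which encodes ceruloplasmin, 2.51-fold. Among the lower genes Cx3cr1, the fractalkine receptor (gene ID 13051, chromosome 9 from 120048683 to 120068296), fell from 72.8 to 21.0 ± 0.55 FPKM, with a log2 fold change of -1.75 ± 0.05 (SE, adjusted p = 0.000552). The lysozyme gene Lyz2 fell from 1693 to 658 ± 16.3 FPKM, and its neighbour Lyz1 from 169 to 67.7 ± 2.72 FPKM; reads of these near-identical genes can be assigned to either. Dmpk fell from 6.63 to 1.81 ± 0.06 FPKM. Fabp5, a fatty acid binding protein, and Hmgn2, a nucleosome-binding protein, fell to 0.49 of the control each. H3f3c and Hist1h2ai, also among the smallest p-values in the fit of all genes, were listed at 0 in both CD137 libraries and at 1.63 and 0.93 FPKM in the control, and both have near-identical copies.

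**Figure D2:**
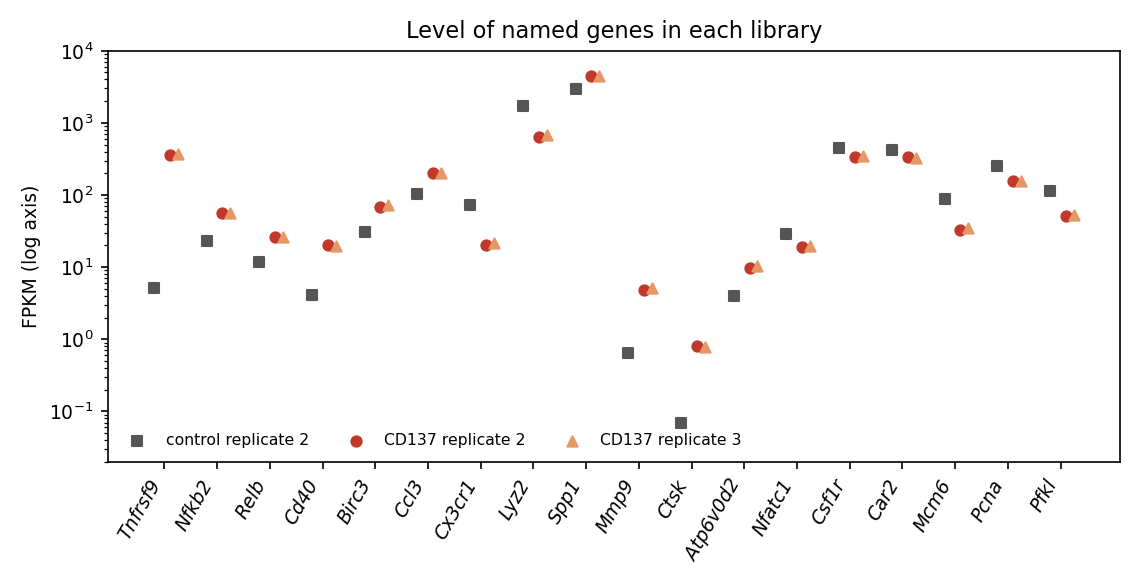
FPKM of 18 named genes in each library, on a log axis: control replicate 2 (squares), CD137 replicate 2 (circles) and CD137 replicate 3 (triangles). Tnfrsf9 is at 5.06 FPKM in the control and at 364 and 370 FPKM in the CD137 libraries, and for every gene plotted the CD137 points lie together on 1 side of the control.

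Most expressed genes on the list of NF-kB targets and TNF receptor signalling were higher in CD137 cells. Of 37 expressed members of the list of NF-kB targets and TNF receptor signalling genes, 23 rose, 5 fell and 9 did not pass; in the fit of all genes 21 were higher and 3 lower when adjusted over the list alone. Nfkb2, the p100/p52 subunit (gene ID 18034, chromosome 19 from 46304320 to 46312090), rose from 22.9 to 56.5 ± 0.25 FPKM, a log2 fold change of 1.27 ± 0.04 (SE, adjusted p = 0.000552). Relb, its partner in the non-canonical pathway, rose 2.25-fold and Birc3, which encodes cIAP2, 2.33-fold. The inhibitor gene Nfkbie rose 2.19-fold and the adhesion molecule Icam1 1.68-fold. Members of the Bcl2a1 family of survival genes rose 7.85-fold (Bcl2a1a), 2.34-fold (Bcl2a1b) and 1.99-fold (Bcl2a1d), but these copies are near-identical and the split of reads between them is uncertain. The list was called by camera with a preset correlation (median log2 fold change 0.32, adjusted p = 0.000678). It lost the call with an estimated correlation (adjusted p = 0.542). The KEGG term NF-kappa B signaling pathway (103 genes, median 0.0835) was not called by camera over all genes (adjusted p = 0.178). Among expressed genes that term just passed (adjusted p = 0.0499). The KEGG term TNF signaling pathway (129 genes, median 0.0213) was not called (adjusted p = 0.573). For the TNF and TNF receptor superfamily without Tnfrsf9, 9 of 20 expressed members rose and 1 fell, with 2 higher when adjusted over the list alone (median 0.15, camera adjusted p = 0.0452; adjusted p = 0.542 with an estimated correlation). Cd40, a receptor of the same family, rose from 4.15 to 19.7 ± 0.42 FPKM. The death receptor Fas rose from 0.72 to 3.66 ± 0.007 FPKM and lymphotoxin alpha (Lta) from 0.71 to 4.93 ± 0.69 FPKM. Tnfsf9, the ligand of CD137, was already at 56.5 FPKM in the control and rose 1.30-fold.

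Lists of co-stimulatory and inhibitory ligands, immediate-early genes, type I interferon response genes, and cyclin-dependent kinase inhibitors and p53 targets were higher as well. Of 17 expressed co-stimulatory and inhibitory ligands 12 rose and 2 fell (11 and 1 adjusted over the list alone; median 0.39, camera adjusted p = 0.0039). Cd274, which encodes PD-L1, rose 2.40-fold and Cd47 1.43-fold, whereas Vsir, which encodes VISTA, fell to 0.541 of the control. Immediate-early genes rose in 17 of 32 expressed members and fell in 3 (15 and 2 adjusted over the list alone; median 0.28, camera adjusted p = 0.0007), among them Fos (3.29-fold), Myc (2.55-fold) and the phosphatase gene Dusp4 (2.51-fold). In the type I interferon list 17 of 34 expressed members rose and 1 fell (12 and 0 adjusted over the list alone; median 0.25, camera adjusted p = 0.0039). Irf7 rose 2.68-fold and Oas2 2.53-fold, while Ifitm3, the most highly expressed member, fell to 0.909 of the control. Of 21 expressed cyclin-dependent kinase inhibitors and p53 targets 13 rose and 4 fell (11 and 3 adjusted over the list alone; median 0.26, camera adjusted p = 0.0228), with Plk2 at 3.79-fold and Zmat3 at 1.72-fold. These 4 lists each had an adjusted p = 0.542 with an estimated correlation. The KEGG term p53 signaling pathway (108 genes, median 0.0298) was not called by camera (adjusted p = 0.991).

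Genes of DNA replication were lower in CD137 cells. Of 34 expressed members 32 fell and 0 rose (30 lower adjusted over the list alone), with a median log2 fold change of -0.65 and a camera adjusted p = 3.27e-16. Mcm6, a subunit of the replicative helicase (gene ID 17219, chromosome 1 from 128331575 to 128359705), fell from 89.4 to 33.6 ± 1.25 FPKM, a log2 fold change of -1.38 ± 0.05 (SE, adjusted p = 0.000552). Mcm3 fell to 0.555, the sliding clamp Pcna to 0.627, the DNA ligase Lig1 to 0.627 and the ribonucleotide reductase Rrm1 to 0.616 of the control. Tk1 was at 111 FPKM in the control and 106 ± 1.73 FPKM in CD137 cells and did not pass. Outside the list, the repair gene Rad54l and the transcription factor Mybl2 fell to 0.389 and 0.401 of the control. In the list of mitotic genes 19 of 29 expressed members fell and 2 rose (19 and 1 adjusted over the list alone; median -0.25, camera adjusted p = 5.95e-07), with Bub1 at 0.626, Ccna2 at 0.699, Top2a at 0.720 and Birc5 at 0.777 of the control. Both calls were lost with an estimated correlation (adjusted p = 0.542).

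Most expressed genes on the lists of cholesterol and lipid synthesis and of glycolysis and hypoxia response were lower in CD137 cells. The KEGG term glycolysis / gluconeogenesis was not called by camera (65 genes, median -0.0078, adjusted p = 0.412). Of the KEGG lipid terms, steroid biosynthesis was called lower (25 genes, median -0.1543, camera adjusted p = 0.0155). Fatty acid biosynthesis (15 genes, median 0.0049, adjusted p = 0.671) and fatty acid metabolism (62 genes, median -0.0122, adjusted p = 0.567) were not called. Neither were biosynthesis of unsaturated fatty acids (median -0.0304, adjusted p = 0.526) and terpenoid backbone biosynthesis (median -0.0934, adjusted p = 0.222). Of 30 expressed genes of cholesterol and lipid synthesis 27 fell and 0 rose (25 lower adjusted over the list alone; median -0.53, camera adjusted p = 1.28e-13). Outside the list, Acat2, an acetoacetyl-CoA thiolase, fell from 15.1 to 5.08 ± 0.88 FPKM. Within it, the ATP citrate lyase Acly fell to 0.575, the desaturases Scd1 and Scd2 to 0.527 and 0.578, and Fdps to 0.696 of the control. In the list of glycolysis and hypoxia response genes 26 of 34 expressed members fell and 2 rose (26 and 1 adjusted over the list alone; median -0.38, camera adjusted p = 7.85e-11). The phosphofructokinases Pfkl and Pfkp fell to 0.454 and 0.644, the triosephosphate isomerase Tpi1 to 0.652 and the pyruvate kinase Pkm to 0.807 of the control. Gapdh, the most highly expressed member, was at 5543 FPKM in the control and 5275 ± 51.8 FPKM in CD137 cells and did not pass. Chaperones of the unfolded protein response and heat shock list fell in 13 of 25 expressed members and rose in 4 (15 and 4 adjusted over the list alone; median -0.18, camera adjusted p = 0.000584). Calr, Hspa8 and Hsp90b1 fell to 0.526, 0.552 and 0.643 of the control, whereas Hspa5, which encodes BiP, rose 1.25-fold. Oxidative phosphorylation genes differed little, with 11 of 38 falling, 3 rising and 0 past the threshold when adjusted over the list alone (median -0.06, camera adjusted p = 0.00445); Ndufa4 fell to 0.749 of the control, and fry did not call this list (adjusted p = 0.111). With an estimated correlation all 4 lists had an adjusted p = 0.542.

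**Figure D3:**
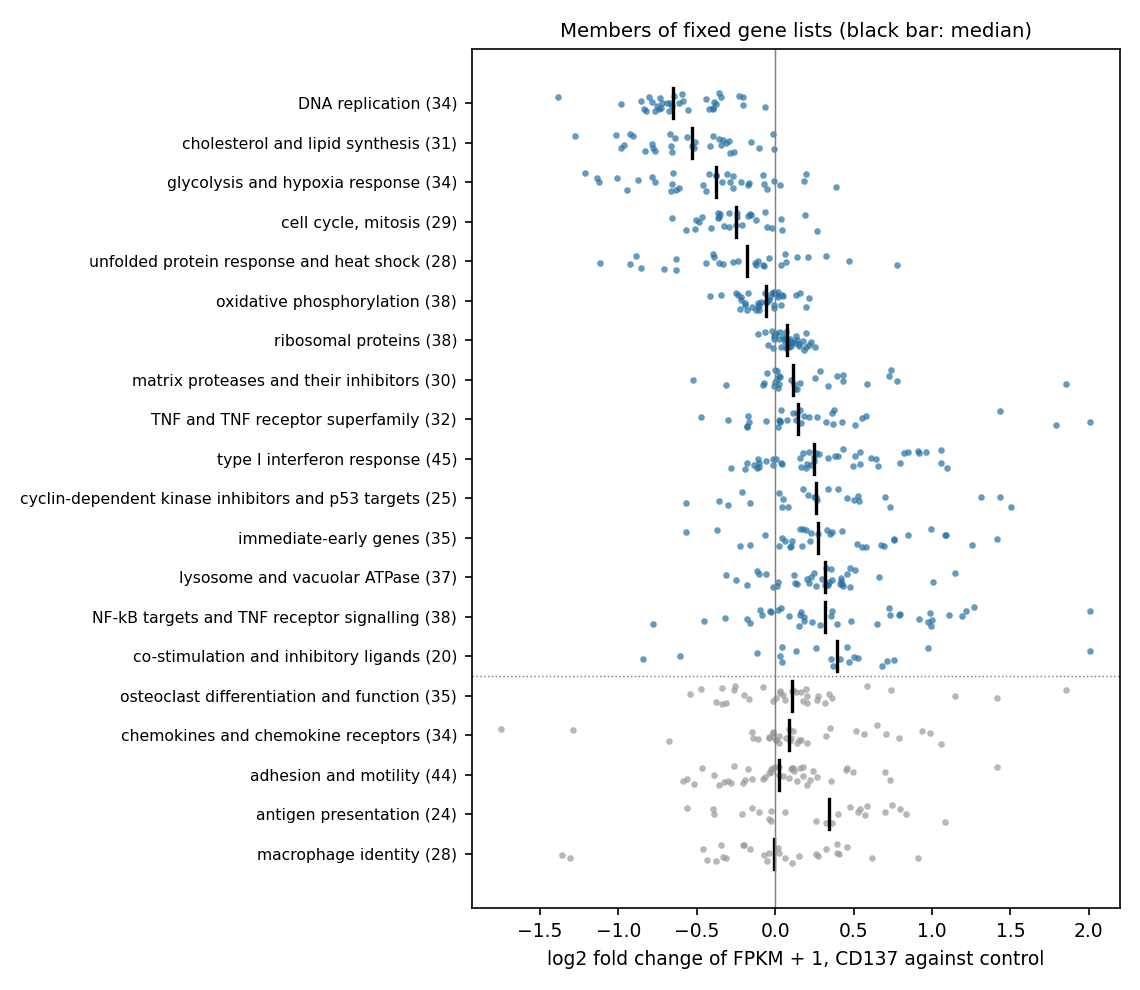
Log2 fold change on the FPKM + 1 scale, CD137 against control, of the measured members of fixed gene lists, with the number measured in parentheses; points are genes and black bars medians. The 15 lists above the dotted line had a camera adjusted p under 0.05, from DNA replication at a median of -0.65 to co-stimulation and inhibitory ligands at 0.39, and the 5 lists below it did not.

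The osteoclast list, which bears on the study's question, went both ways. Of 27 expressed members 9 rose and 8 fell (12 and 8 adjusted over the list alone), with a median log2 fold change of 0.11, and the list was not called by camera, which compares it with other genes (adjusted p = 0.402), but was called by fry, which does not (adjusted p = 0.0494). Mmp9, a secreted matrix protease, rose from 0.65 to 4.97 ± 0.25 FPKM, a log2 fold change of 1.85 ± 0.10 (SE, adjusted p = 0.000875). Atp6v0d2, a subunit of the vacuolar proton pump used in cell fusion and resorption, rose from 4.00 to 10.1 ± 0.34 FPKM. Ctsk, the bone-degrading cathepsin K, stayed under the expression limit, at 0.07 FPKM in the control and 0.79 ± 0.02 FPKM in CD137 cells, and Oscar was listed at 0 in the control and at 0.12 FPKM in both CD137 libraries. Nfatc1, the transcription factor that drives osteoclast differentiation, fell from 28.4 to 19.2 ± 0.32 FPKM. The M-CSF receptor gene Csf1r fell to 0.771 and the carbonic anhydrase Car2 to 0.789 of the control. Inhibitors of osteoclast formation rose in 6 and fell in 4 of 18 expressed members (6 and 2 adjusted over the list alone), with no call for the list by camera (adjusted p = 0.896) and a call by fry (adjusted p = 0.019); Lilrb4a rose 1.90-fold.

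Genes tied to migration also moved in both directions. Among 16 expressed chemokines and chemokine receptors 8 rose and 3 fell (10 and 3 adjusted over the list alone; median 0.09, camera adjusted p = 0.16). Ccl3 rose from 102 to 203 ± 0.36 FPKM, Ccl4 1.76-fold, Ccl5 2.48-fold and Ccl9 1.28-fold. Cxcl10 rose from 0.30 to 1.70 ± 0.07 FPKM. Besides Cx3cr1, the chemokine Cxcl14 fell to 0.357 and the complement receptor C5ar1 to 0.563 of the control. Among 40 expressed adhesion and motility genes 12 rose and 13 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.896, fry adjusted p = 0.0402). The integrins Itgax and Itgam rose 4.98-fold and 1.38-fold and the GTPase Rhoc 1.64-fold, while the actins Actb and Actg1 fell to 0.722 and 0.666, and gelsolin (Gsn) to 0.677 of the control. Vimentin (Vim) was at 784 FPKM in the control and 737 ± 8.63 FPKM in CD137 cells and did not pass. This list's median of 0.02 and mean of 0.04 were positive while its test pointed down. Matrix proteases and their inhibitors rose in 9 of 17 expressed members and fell in 2 (9 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.0367; adjusted p = 0.542 with an estimated correlation), and the call was also lost among expressed genes (adjusted p = 0.154). Plau, the urokinase gene, rose from 85.9 to 142 ± 2.43 FPKM. Spp1, which encodes osteopontin and was among the most abundant transcripts, rose from 2974 to 4513 ± 11.5 FPKM.

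Lysosomal genes were higher, with 26 of 37 rising and 2 falling (27 and 3 adjusted over the list alone; median 0.32, camera adjusted p = 2.07e-05; adjusted p = 0.542 with an estimated correlation). Atp6v0a1 rose 2.05-fold, the galactosidase Glb1 1.61-fold and cathepsin L (Ctsl) 1.35-fold, while cathepsin B (Ctsb), the most abundant, was at 1471 FPKM in the control and 1492 ± 5.66 FPKM in CD137 cells, did not pass, and changed sign under other scalings. Ribosomal protein genes rose slightly, in 12 of 38 members with 1 falling (0 adjusted over the list alone; median 0.08, camera adjusted p = 0.0155; adjusted p = 0.542 with an estimated correlation); Rpl30 rose 1.19-fold. This call was also lost with median-ratio scaling (adjusted p = 0.0973). Among antigen presentation genes 12 of 19 expressed members rose and 2 fell (13 and 3 adjusted over the list alone), without a call for the list (median 0.34, camera adjusted p = 0.104), although among expressed genes it was called (adjusted p = 0.0115); over all genes it had an adjusted p = 0.755 with an estimated correlation. Cd74, the invariant chain, rose from 476 to 1009 ± 28.7 FPKM and B2m from 526 to 855 ± 10.98 FPKM. The class I genes H2-Q7 and H2-D1, whose reads can be shared with close paralogs, rose 1.80-fold and 1.501-fold, and the immunoproteasome subunit Psmb8 fell to 0.673 of the control. Macrophage identity genes rose in 10 and fell in 9 of 26 expressed members (7 and 9 adjusted over the list alone; adjusted p = 0.64); besides Lyz2 and Csf1r, which fell, Laptm5 was at 537 FPKM in the control and 562 ± 31.8 FPKM in CD137 cells and did not pass. None of the 15 calls of lists was kept with an estimated correlation, a test with little power at 1 residual degree of freedom.

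Outside the fixed lists, 319 KEGG terms given in the file were tested with camera, and 12 had an adjusted p under 0.05, 5 up and 7 down. DNA replication (55 genes, adjusted p = 1.45e-07), mismatch repair (26 genes, adjusted p = 0.000448), the Fanconi anemia pathway (58 genes, adjusted p = 0.0042), spliceosome (197 genes, adjusted p = 0.00481) and steroid biosynthesis (25 genes, adjusted p = 0.0155) were down. Allograft rejection (53 genes, adjusted p = 0.0042) and graft-versus-host disease (54 genes, adjusted p = 0.00432), terms that consist largely of histocompatibility genes, were up. With an estimated correlation 0 of the 319 terms passed, and each of these 12 had an adjusted p = 0.906. Cell cycle (142 genes, adjusted p = 0.00575) was also among those down at the preset. Several called lists had no called term on their theme. Besides the terms given above, HIF-1 signaling (adjusted p = 0.785), ribosome (0.222) and oxidative phosphorylation (0.679) were not called by camera at the preset. Lysosome was called only among expressed genes (adjusted p = 0.0654 over all genes, 0.018 among expressed genes). The same held for cell adhesion molecules, up (174 genes, adjusted p = 0.418 over all genes, 0.0152 among expressed genes). Osteoclast differentiation (135 genes, median 0.0944) was called in neither camera test (adjusted p = 0.261 and 0.16), nor was chemokine signaling (208 genes, adjusted p = 0.583 and 0.412).

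Markers of other cell types were low, with 1 exception by library. Of 16 measured epithelial and mammary carcinoma genes, Krt8 was at 0.25 FPKM in the control, 2.60 FPKM in CD137 replicate 2 and 0.66 FPKM in CD137 replicate 3, and Cldn4 at 0.40, 3.57 and 0.47 FPKM. Neither passed; 1 of 5 expressed members rose and 0 fell (1 and 0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.40). Lcn2, also on this list and on that of inflammatory activation, was higher in both CD137 libraries. The lists of lymphocyte, of dendritic cell, granulocyte and mast cell, of endothelial and erythroid, and of fibroblast, osteoblast and stroma markers had 2 expressed members each, of which 1, 2, 1 and 0 rose and 0 fell, with 0 adjusted over the list alone and camera adjusted p of 0.455, 0.736, 0.908 and 0.975.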

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

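The settings that combine the filter with a second choice, limma-voom on recovered reads, the filter and scaling for lists, and all alternatives for pathway terms were chosen after seeing the data. No gene passed in the limma fit of all genes with a pseudocount of 1 or 0.1, with 5281 and 5430 genes at an unadjusted p under 0.05. Among expressed genes 4563 passed (2614 higher, 1949 lower, 147 at least 2-fold). With expressed genes and a pseudocount of 0.1 these counts were 4545 (2618, 1927, 312); with median-ratio scaling 4470 (2260, 2210, 136); with upper-quartile scaling 5307 (2691, 2616, 137); without a trend 3801 (2174, 1627, 144); with robust moderation 4831 (2758, 2073, 144); and with limma-voom on recovered reads 5059 (2866, 2193, 450). Of the 4563 genes, 4529, 4209, 4487, 3595 and 4558 were also called in the first 5 of these alternatives, and 4109 of the 4281 that could be tested with limma-voom. The share of higher genes among calls went from 57.3 to 50.6 percent with median-ratio scaling. The count at 2-fold is larger with a smaller pseudocount and with limma-voom by construction, since adding 1 FPKM shrinks low genes.

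Tnfrsf9 had a log2 fold change of 5.92 in the fit of all genes, short of the threshold (adjusted p = 0.0802). It passed among expressed genes at 5.92, and with a pseudocount of 0.1 (6.15), median-ratio and upper-quartile scaling (5.90 each), no trend (5.92) and robust moderation (5.92), with adjusted p from 1.57e-20 to 0.00186. Without CD137 replicate 3 its value was 5.91 and without replicate 2 it was 5.94; its reads were not recovered, so limma-voom gave none. Of 110 other named genes, 687 of 1059 values under alternatives came past the threshold that none passed in the fit of all genes; 2 changed sign, Ctsb at -0.01 under median-ratio and -0.01 under upper-quartile scaling, where the shift of all genes explains it by construction. H3f3c and Hist1h2ai, listed at 0 in both CD137 libraries, had values of -1.40 and -0.95 without either CD137 library, as with both.

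Camera called 15 of 36 lists, 12 KEGG terms and 271 GO terms, and 0 of each with an estimated correlation. That version draws on the 1 residual degree of freedom, which leaves it little power. Its smallest unadjusted p for a list was 0.0659, for DNA replication. The lost calls therefore do not argue against the lists, and the calls at the preset rest on an assumed correlation of 0.01. With a pseudocount of 0.1, median-ratio scaling, expressed genes only and fry, 15, 15, 16 and 20 lists were called, not all the same ones. Expressed genes only gave 23 KEGG and 291 GO terms. Between the CD137 libraries 20 genes differed at least 2-fold, 3 when genes with a mean under 100 recovered reads were left out, and 4 at 4-fold, which fewer genes reach by construction.

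Leaving out either CD137 library leaves 1 library per group, so counts of calls could not be given and only values remain, also without CD137 replicate 2, in which epithelial genes were seen. No paired analysis was possible because the groups share only replicate number 2 in the table. The tests set out beforehand for counts were not run, because the table holds FPKM: edgeR with median-ratio, upper-quartile or library-total normalization, other count filters and prior counts, the DESeq2 Wald test, and limma-voom on deposited counts. With 1 control library, no setting can show how much controls differ from each other.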

Other observations

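Tests of counting noise, of the introduced Cd137 and of the authors' normalization were chosen after the results they bear on had been seen; the tests of fewer genes adjusted, low genes, length and GC content, and epithelial terms were written before theirs.

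Further gene groups went both ways. Apoptosis regulators rose in 14 and fell in 5 of 26 expressed members (13 and 5 adjusted over the list alone) with a camera adjusted p = 0.0576, 0.0401 among expressed genes, and adjusted p = 0.542 with an estimated correlation. Fry, which tests against no change and not against other genes, gave 0.0402; Mcl1 fell to 0.672 of the control. Inflammatory activation genes rose in 9 and fell in 4 of 19 expressed members (8 and 3 adjusted over the list alone; camera adjusted p = 0.0594, 0.0481 with median-ratio scaling, 0.06 among expressed genes, and adjusted p = 0.615 with an estimated correlation). Within this list the Fc receptor Fcgr1 rose 2.05-fold, while Acod1, the itaconate-producing enzyme of activated macrophages, fell from 3.8 to 1.08 ± 0.007 FPKM (SD, n = 2). Monocyte growth factors and cytokines rose in 9 and fell in 5 of 21 expressed members (10 and 6 adjusted over the list alone; adjusted p = 0.736), with Osm at 2.51-fold and Csf1 at 2.55-fold while its receptor gene fell. In the NRF2 list 8 of 27 expressed members rose and 10 fell (6 and 9 adjusted over the list alone; adjusted p = 0.124), with Sqstm1, the autophagy receptor p62, at 1.90-fold. In the integrated stress response list 9 rose and 12 fell of 27 (8 and 9 adjusted over the list alone; adjusted p = 0.435), with Ddit4 at 0.48 of the control. The following lists were not called by camera, with members rising and falling among expressed ones and, after the semicolon, adjusted over the list alone: alternative activation 3 and 1 of 9; 1 and 0 (adjusted p = 0.104), complement and Fc receptors 6 and 2 of 13; 4 and 1 (0.222), and cholesterol efflux 4 and 5 of 19; 4 and 6 (0.373). Fry called the complement and the efflux list (adjusted p = 0.0402 and 0.034). Retroviral restriction and DNA sensing had 5 and 1 of 19; 4 and 1 (0.736). Replication-dependent histones, which have near-identical copies, had 1 rising and 1 falling of 9 expressed members, and 0 and 1 adjusted over the list alone (camera adjusted p = 0.896). Their median was 0.12 and their mean 0.09 while the test pointed down. Of 22 measured members 9 were expressed in this RNA, which was selected with oligo-dT beads. How well that selection captures histone transcripts was not tested, so the list says little about these genes.

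Car6 and Tnfrsf9, which had the smallest p-values of all genes, lie 719 kb apart on chromosome 4. The 4 expressed genes between them, named after their values were seen, did not share the increase. Eno1 was at 1718 FPKM in the control and 1408 ± 19.0 FPKM in CD137 cells (SD, n = 2), Rere at 62.4 and 49.6 ± 0.05 FPKM, Errfi1 at 5.99 and 6.05 ± 0.25 FPKM, and Park7 at 178 and 151 ± 4.14 FPKM. No explanation was tested.

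CD137 replicate 2 held more epithelial transcripts than the other libraries. The 12 summed members of the list, without Lcn2, gave 403 recovered reads there, against 76 in CD137 replicate 3 and 62 in the control. Counting noise is argued against, since 5 members (Krt8, Krt18, Krt19, Cdh1 and Cldn4) had an adjusted p under 0.05 between the CD137 libraries in the authors' deposited table, a comparison of those libraries only. An effect of the introduced Cd137 common to the CD137 libraries is argued against: Tnfrsf9 was at 364 and 370 FPKM in CD137 replicates 2 and 3, while the epithelial sum of replicate 3 was 0.188 of that of replicate 2 (upper 95% bound 0.24) and 1.24 of that of the control (0.876 to 1.76), with intervals for counting error only. RNA of epithelial cells may be the source but cannot be told apart from other sources: of 13 genes outside the list with the same excess 1 carried the GO term epithelial cell differentiation, an odds ratio of 3.88 (95% interval 0.503 to 29.99), too few to decide.

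The fit of all genes called none and that of expressed genes called 4563. A smaller number of adjusted tests does not give the calls by itself. The p-values of the fit of all genes, adjusted over the expressed genes alone, gave 0 calls. That outcome was fixed by the smallest adjusted p of 0.0802 in the limma fit of all 16003 genes. Adjusting the same p-values over 10720 genes could bring none under 0.05, so the step was arithmetic and could not have come out otherwise. Uneven spread of low genes may account for the difference but was not separated from other features of low genes. Leaving out 5283 genes at random in place of the low genes gave at most 0 calls in 20 draws. Such draws keep the mix of low and high genes, so they show only that fitting fewer genes is not enough. The prior degrees of freedom were 0.931 over all genes and 3.95 over expressed genes.

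Replication, cholesterol synthesis and glycolysis lists were lower and the NF-kB list higher in CD137 cells. Transcript length and GC content are argued against as the whole cause, since removing their trend over 10437 genes kept at least 92.2 percent of each list's median; that trend held only 0.89 percent of the variance, so its removal moved genes little. The authors' scaling between libraries is argued against, since another scaling shifted expressed genes by 0.03 on the log2 scale, 8.3 percent of the smallest of the 4 medians. Each scaling tried was 1 factor per library, which moves all genes the same way. Effects of the normalization that differ between genes were therefore not tested. A difference of the single control culture, such as its density or growth state, and an effect of Cd137 may each give such a pattern and cannot be told apart, because the table holds 1 control library.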
